A study of Arabidopsis thaliana with 2 samples.

How the data were processed

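RNA-seq was made from whole 12-day-old Arabidopsis thaliana seedlings grown at 20 °C in long days without treatment. There were 2 libraries, 1 from Col-0, the standard laboratory accession, and 1 from seedlings of the same accession labelled FMO5-OE T1. The label was read as overexpression of FMO GS-OX5 (locus AT1G12140). What T1 stands for is not given in the sources used here. Total RNA was extracted with TRIzol and column-cleaned after DNase treatment, per the labels' protocols.

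The deposited counts are whole-number counts of reads per transcript model, per the file headers, and each file also holds the model's length, its RPKM and the percent of its length covered by reads. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting program and whether strand was used are not given in the sources used here. The RPKM column was recomputed from count, length and total, and 100% of values were returned within rounding in both libraries. The 4591 models with 1 read were each covered over 49 bases, which gives the read length. Models without reads are not listed, and a model missing from 1 library was taken as a count of 0.

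Counts were summed over the listed models of a locus. This gave 23667 loci, of which 23519 were nuclear and 3330 had several listed models. Reads that fit several listed models, of a locus or of loci that overlap on opposite strands, appear to have been left out by the counting, so that counts of such loci are incomplete in both libraries. Of 140 single-model loci that share sequence only with the opposite strand, with partners of the annotated length, 0 were covered over 5 points beyond the part that no other model shares. With partners of another length, whose overlap is not known, it was 25 of 218. This comparison was chosen after the results were seen. Neighbours of the same product were marked where they lay within 20 kb, since reads can be shared between them. The mark needs the same wording of the product and so misses relatives such as COR15A and COR15B or the numbered FMO genes, and it does not see overlaps on opposite strands. Symbols, products and coordinates came from the TAIR10.1 annotation, which held 23466 of the loci. Of the 27470 listed models, 26776 had a reference transcript of the same name and 5570 of those had the same length.

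Counts were turned into CPM, counts scaled to a common library size, with TMM factors from edgeR 4.0.16, which were 0.967 for Col-0 and 1.03 for FMO5-OE. The DESeq2 1.42.0 size factors, used as an alternative, were 0.944 and 1.06. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The library totals were 11.56 M reads for Col-0 and 12.21 M for FMO5-OE. A single read was worth 0.0894 CPM in Col-0 and 0.0792 CPM in FMO5-OE, and 5 CPM stood for 55.9 and 63.1 reads.

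With 1 library per genotype no test between genotypes exists, and no p-value is given. Log2 ratios are of CPM + 1, FMO5-OE over Col-0, which understates the difference of low genes, while folds are ratios of CPM. Intervals on folds are exact Clopper-Pearson intervals of the 2 counts at 95%. They cover counting error only and say nothing of the spread between plants or cultures. A nuclear locus was counted as at least 2-fold apart when its log2 ratio was 1 or more in size and its higher library reached 5 CPM.

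A total of 45 gene lists were fixed before the data were examined, 30 of named loci and 15 of words in the annotated product. The median log2 ratio of the members at 1 CPM or more was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile, for lists with 5 or more members, which happens to 5% of lists by chance. Random lists treat genes as independent. Members of a list are often co-expressed, so list medians vary more than random ones and the percentiles overstate how unusual a list is. Intervals of medians are order-statistic intervals at 95%.

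Some product patterns caught more than their names say. The pattern for defensins and thionins also matched products with the word methionine, mostly methyltransferases, and its value does not describe defensins. It was kept as fixed. The peroxidase pattern can hold other peroxidases, the pattern for TIR-type disease resistance proteins also took other nucleotide-binding classes, the HSP20 pattern took HSP20-like proteins in general, and the pattern for cytosolic ribosomal proteins found only 17 loci. Of 469 list entries, the annotation repeated the symbol of 448, and 0 were dropped.

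The genes named were fixed by rule: the FMO family, the 15 protein-coding loci with the largest and the 15 with the smallest log2 ratio among those at least 2-fold apart, and per described list the 4 members with the largest ratio in size at 5 CPM or more and any member at least 2-fold apart. The text gives a selection of these. Loci named outside the rule are said to be so.

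The calculations were tested on simulated counts drawn for the 13019 nuclear loci at 5 CPM or more, with 200 loci changed. The size rule counted 0% of 50 loci simulated at 1.5-fold, 24% of 50 at 2-fold, 98% of 50 at 3-fold and 100% of 50 at 4-fold, and 0 of 12799 unchanged loci. A simulated list of 20 loci raised by 0.5 in log2 ratio lay at the 100th percentile, and a list of 20 unchanged loci at the 15.4th. These simulated counts held counting noise only and no difference between plants. They check the calculation and do not say how often the rule or a percentile would err between 2 libraries of 1 genotype.

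Alternatives were a pseudocount of 0.1 or 5, a median ratio set to 1, DESeq2 size factors and equal totals over nuclear genes. Further ones were total count CPM, other minimums, a 3-fold rule, all genes in the files, 10 bins, and lists without marked neighbours. Single-model loci only, the model with most reads, and removal of the trend over transcript length and GC content in 50 bins were added after the data were seen.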

Results

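The comparison asked how the seedling transcriptome differed when FMO GS-OX5, a flavin-containing monooxygenase of the clade that S-oxygenates glucosinolates, was overexpressed without stress treatment. The Col-0 library held 11.56 M counted reads on 25712 transcript models and the FMO5-OE library 12.21 M on 26059. Chloroplast transcripts took 2.37% of reads in Col-0 (Wilson 95% interval 2.36% to 2.38%) and 1.91% in FMO5-OE (1.90% to 1.92%). There was 1 library per genotype, so no difference has a replicate check, and the genotype cannot be separated from any other difference between the seedling batches.

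FMO GS-OX5 (AT1G12140) was far higher in the FMO5-OE library. It had 28 reads in Col-0 and 1379 in FMO5-OE, or 2.5 and 109 CPM, a 43.6-fold difference (95% counting interval 30.1 to 65.9) and a log2 ratio of 4.98. The gene lies on chromosome 1 from 4121285 to 4124595 on the plus strand of TAIR10.1, and its transcript model 1 has 6 exons. The reads were all counted on model 1 in FMO5-OE and covered 175 of its 2146 bases, or 8.15%. In Col-0, 26 reads covered 139 bases, or 6.48%. The deposited length of model 1 is 84 bases shorter than that of the annotation, 2230, and the 84 bases by which the annotated model 1 begins before model 2 were taken as those missing. In the remaining length, the bases of model 1 outside model 2 are 6 at the start of exon 2, 122 at the end of exon 5 and the 451 of exon 6. Reads absent from model 2 could cover 33.6% of model 1, and reads absent also from AT1G12150, which overlaps it on the other strand, 12.9%. Its relatives differed far less between the libraries. FMOGS-OX1 had 0.735 of its Col-0 level, FMOGS-OX3 0.877, FMOGS-OX4 1.1 and FMOGS-OX2 1.44. FMOGS-OX7 and FMOGS-OX8, which were marked because they lie next to loci of the same product, had 0.711 and 1.31. FMO GS-OX5 lies between FMOGS-OX6 and FMOGS-OX7, and FMOGS-OX2, FMOGS-OX3 and FMOGS-OX4 lie side by side. Stretches of 49 bases shared exactly with a relative made up 0.297% of FMOGS-OX1, 0.295% of FMOGS-OX2, 0.0438% of FMOGS-OX3 and 0% of the others. The mark of FMOGS-OX7 and FMOGS-OX8 thus rests on the wording of their products and not on exact shared stretches. FMOGS-OX6 had 2 and 4 reads, too few to compare.

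**Figure D1:**
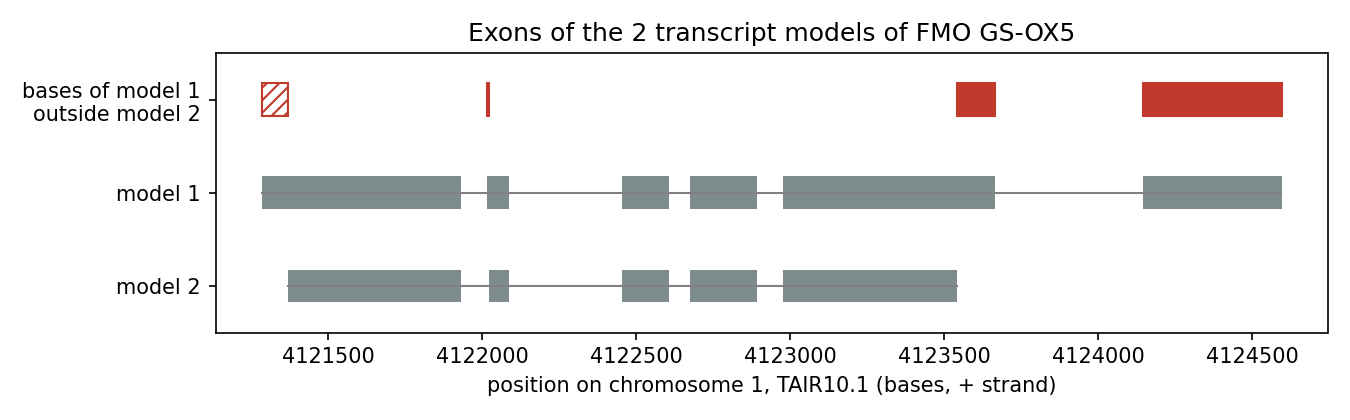
Exons of the 2 transcript models of FMO GS-OX5 along chromosome 1 (TAIR10.1, plus strand, bases), with model 1 in the middle row, model 2 in the lower row and the bases of model 1 outside the exons of model 2 in red. The filled red stretches are 6, 122 and 451 bases long, and the hatched one is the 84 bases of the annotated model 1 that the deposited length leaves out.

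Among other protein-coding genes, the largest differences lay well below that of FMO GS-OX5. The pseudogene AT5G35935, named after its value was seen, was 31.9-fold higher in FMO5-OE (16.6 to 70.4), an interval that overlaps that of FMO GS-OX5. BT2, a BTB and TAZ domain protein whose transcript responds to sugar and nitrogen supply, was 4.44-fold higher in FMO5-OE (4.12 to 4.79). SDI1, a marker of sulfur deficiency, was 4.81-fold higher (3.72 to 6.30), and WRKY40, a defence-related transcription factor, 4.79-fold (3.64 to 6.41). AT1G02660, an alpha/beta-hydrolase, was 4.21-fold higher and the peroxidase PRX52 5.44-fold, from 15 to 92 reads. On the other side, COR15B, a cold-regulated chloroplast protein, was 6.58-fold lower in FMO5-OE (3.97 to 11.5), from 105 to 18 reads. It lies beside its relative COR15A, with which it shares 0 stretches of 49 bases. S8H, an enzyme of the iron-responsive coumarin pathway, was 4.25-fold lower (2.82 to 6.59), the arabinogalactan protein AGP30 3.11-fold (2.70 to 3.59) and the germin-like protein GLP9 2.52-fold (2.23 to 2.86).

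In all, 96 of 13019 nuclear loci at 5 CPM or more were counted as at least 2-fold higher in FMO5-OE and 45 as at least 2-fold lower. The other 98.9% fell short of the rule. As the rule is on CPM + 1, loci just beyond 2-fold in CPM can fall short of it, such as NMT3 at 2.01-fold. Higher loci made up 68.1% of those apart. With total count CPM the split was 136 higher and 31 lower, or 81.4% higher, and with equal totals over nuclear genes it was 134 and 33, or 80.2%. The median log2 ratio of all these loci was -0.01 and the interquartile range 0.33. In 100 simulations with counting noise alone, the mean interquartile range was 0.137 and at most 2 loci were counted as higher and 1 as lower. These simulations hold no difference between plants, so they do not say how many loci would differ between 2 libraries of 1 genotype. The rule of size depends on its settings: a minimum of 20 CPM left 56 higher and 21 lower, and a 3-fold rule 16 and 3.

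**Figure D2:**
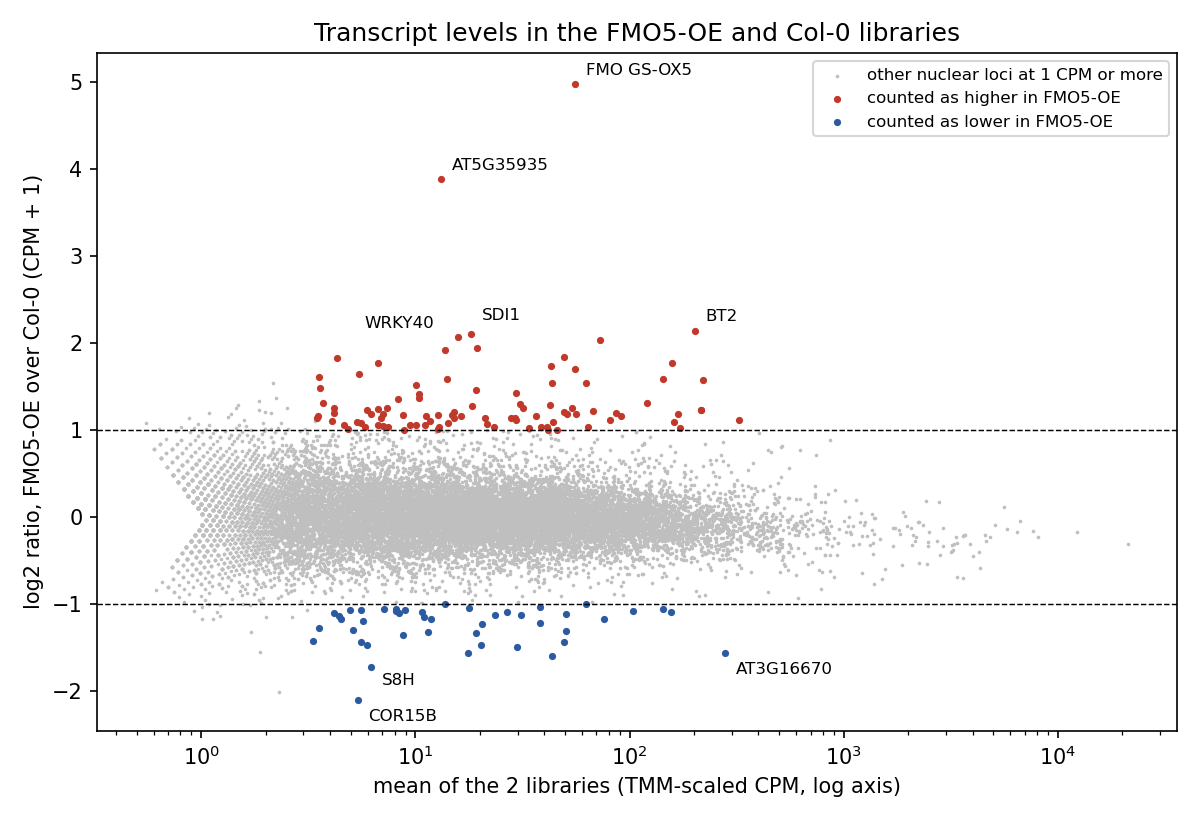
Log2 ratio of FMO5-OE over Col-0 (CPM + 1) against the mean level of each nuclear locus (CPM, log axis), 1 point per locus, with dashed lines at the 2-fold limits. FMO GS-OX5 stands at 4.98 and AT5G35935 at 3.89, and the other loci counted as apart lie between -2.10 (COR15B) and 2.13 (BT2).

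Of the 44 lists with enough members, 10 stood apart as higher in FMO5-OE and 10 as lower, against 2.2 expected by chance for independent genes. The 14 measured genes of senescence and sugar starvation had a median log2 ratio of 1.06 (0.30 to 1.25), with 13 above 0 and 8 at least 2-fold higher. Among them were BT2, the sucrose transporter SWEET15 (2.74-fold), the senescence regulator NAP (2.42-fold), the trehalose-phosphate synthase family members TPS8 (2.17-fold) and TPS11 (2.28-fold), SEN1 (2.28-fold) and the asparagine synthetase ASN1 (2.19-fold). The beta-glucosidase DIN2 was the exception, 2.66-fold lower (2.16 to 3.28). All 14 sulfur deficiency genes lay above 0, with a median of 0.71 (0.30 to 1.23), and 5 were at least 2-fold higher: SDI1, SDI2 (2.31-fold), the sulfate transporter SULTR1;1 (4.1-fold), SHM7 (2.36-fold) and BGLU28 (2.88-fold). All 12 measured phosphate starvation genes lay above 0 as well, with a median of 0.70 (0.42 to 1.21), or 0.42 with a pseudocount of 5. Of these the pyrophosphatase PPSPASE1 was 3.26-fold higher, the non-coding RNA IPS1 2.79-fold and GDPD1 2.36-fold, and the phosphate sensor SPX1 1.90-fold.

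Genes that respond within minutes to stress and touch were higher too. Their median was 0.74 (0.28 to 1.36), 16 of 18 lay above 0 and 6 were at least 2-fold higher: WRKY40, WRKY33 (2.99-fold), WRKY53 (2.87-fold), the zinc finger protein SZF1 (3.02-fold), ERF6 (2.79-fold) and the xyloglucan-modifying enzyme TCH4 (2.36-fold). Each of these 4 lists lay at the 100th percentile of its random lists. The auxin response list had a smaller median of 0.18 (-0.08 to 0.51), at the 98.8th percentile but with an interval that spans 0. Of its 19 measured members 11 lay above 0, and 7 have a neighbour of the same product. GH3.5 was 1.59-fold and HAT2 1.47-fold higher. The auxin median was 0.11 with a pseudocount of 5 and 0.27 with total count CPM.

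Iron deficiency genes were lower in FMO5-OE. Their median was -0.69 (-1.13 to -0.42), or -0.38 with a pseudocount of 5, and 12 of 14 lay below 0. S8H and CYP82C4, enzymes of the coumarin pathway, were 4.25-fold and 2.21-fold lower, the ferric reductase FRO2 1.86-fold and the iron transporter IRT1 1.51-fold. Cold-regulated genes had a median of -0.35 (-0.68 to -0.06) with 14 of 16 below 0, among them COR15A (2.15-fold lower), RD29A (1.62-fold) and KIN1 (1.66-fold). Extensins and arabinogalactan proteins of the cell wall had a median of -0.25, or -0.16 with total count CPM, with 63 of 85 below 0, and 6 were at least 2-fold lower, including AGP30 and AT3G16670, which has a neighbour of the same product.

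Other lists stood apart as lower by small amounts. Photosynthesis genes had a median of -0.23 with 28 of 29 below 0, and LHCB2.2 of the light-harvesting complex was 1.36-fold lower. Cytosolic ribosomal proteins had a median of -0.28, with 9 of 10 below 0. Both calls ended when the trend over transcript length and GC content was removed, with medians of -0.10 and -0.14, and that of photosynthesis also with single-model loci only. Total count CPM gave -0.13 for photosynthesis, and a pseudocount of 5 gave -0.18 for ribosomal proteins. Stomatal lineage genes had a median of -0.26 (-0.85 to 0.05), with the initiating factor SPCH 1.88-fold lower. Dividing cell markers had a median of -0.16 (-0.28 to 0.08), with PCNA1 1.59-fold lower. The intervals of both medians span 0. The stomatal median was -0.44 at a minimum of 5 CPM, and that of dividing cells -0.069 with total count CPM. The stomatal call ended without a minimum on members, and the dividing cell call at a minimum of 5 CPM and with a pseudocount of 5.

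**Figure D3:**
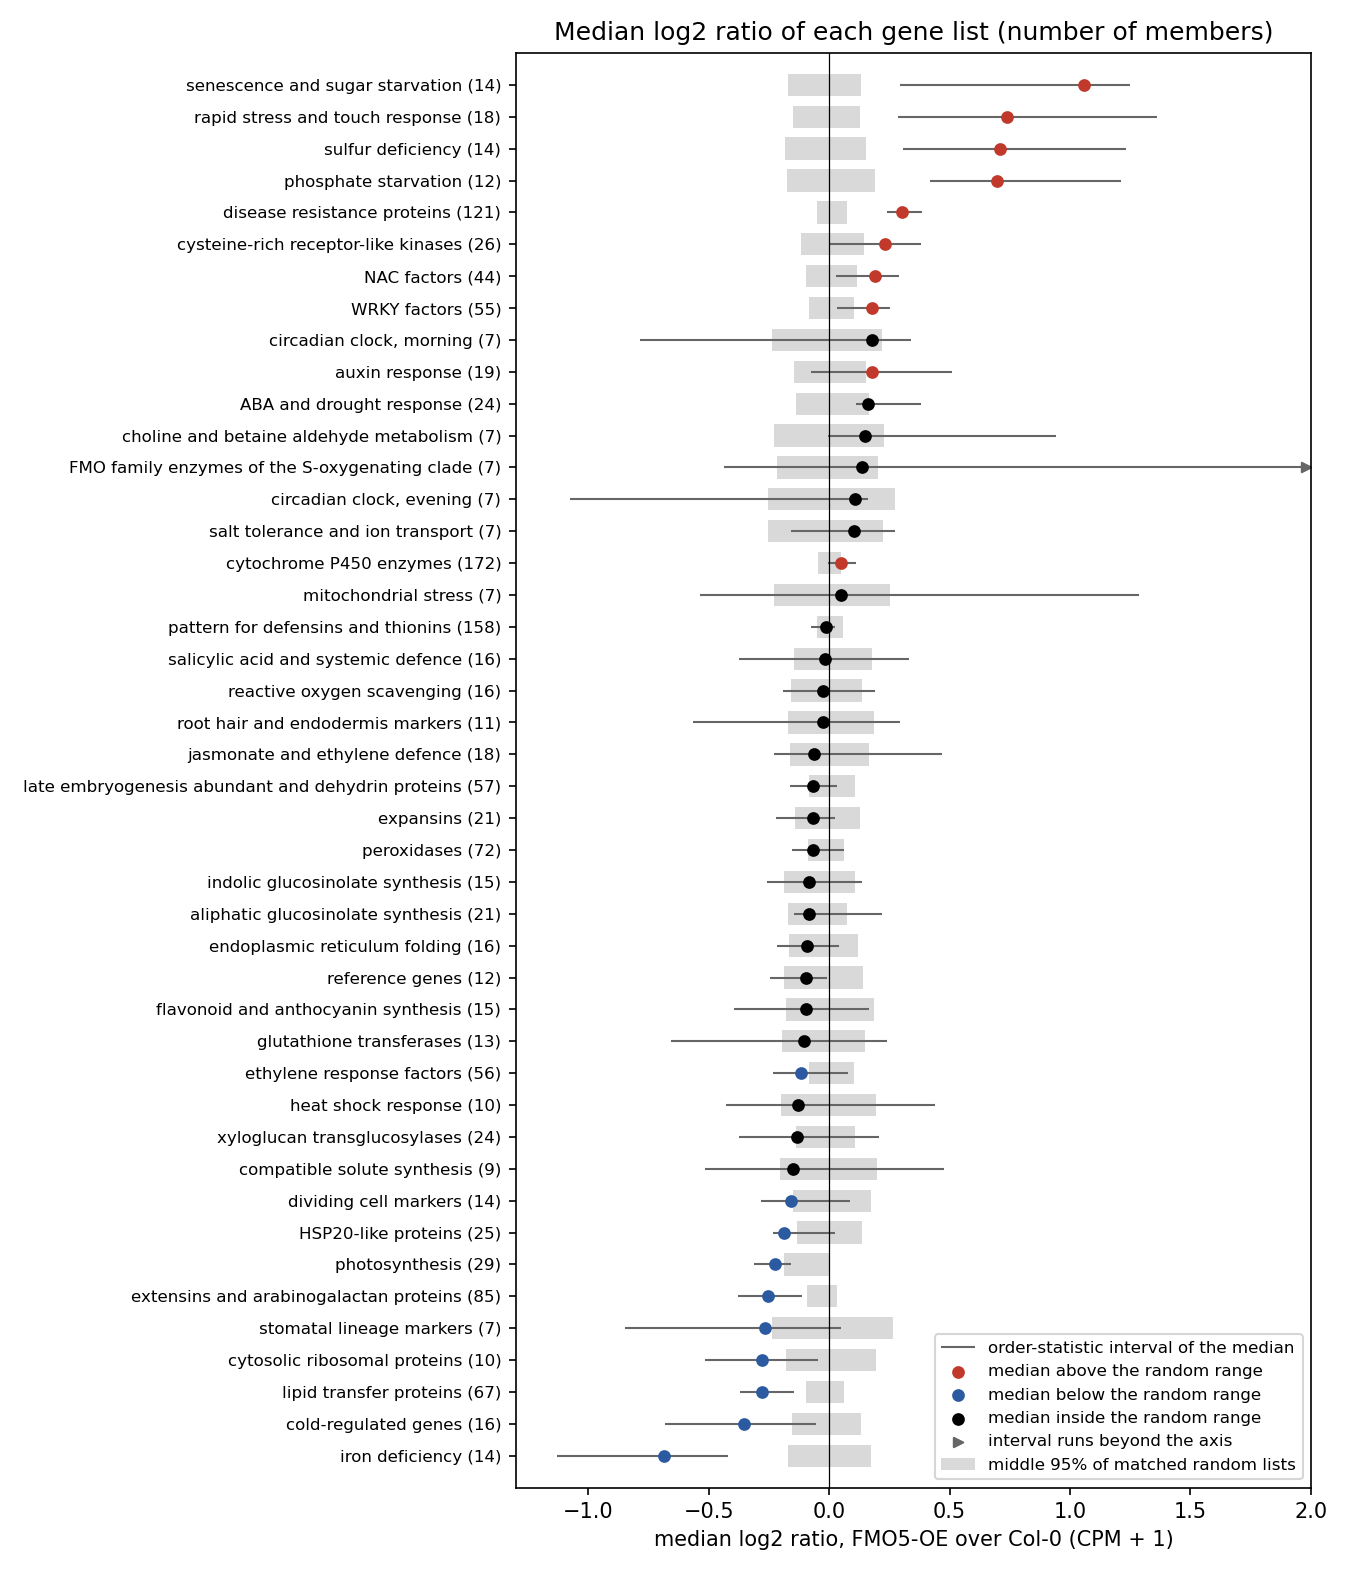
Median log2 ratio (FMO5-OE over Col-0, CPM + 1) of each of the 44 lists, with its 95% order-statistic interval and, as a grey bar, the middle 95% of matched random lists. Senescence and sugar starvation (1.06) and iron deficiency (-0.69) mark the ends.

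Lists of glucosinolate, choline, salt tolerance, compatible solute, heat shock response, protein folding and oxygen scavenging genes did not stand apart. Aliphatic glucosinolate synthesis genes had a median of -0.08 and indolic ones -0.08. Among the indolic genes the regulator MYB51 was 2.99-fold higher and IGMT2 2.74-fold lower. IGMT2 and IGMT1, which was 1.25-fold higher, each have a neighbour of the same product. Choline and betaine aldehyde genes had a median of 0.15, with NMT3, a phosphoethanolamine methyltransferase, 2.01-fold higher. Salt tolerance genes had a median of 0.10, compatible solute genes -0.15, heat shock genes -0.13, endoplasmic reticulum folding genes -0.09 and reactive oxygen scavenging genes -0.02. The ABA and drought list had a median of 0.16 at the 97.2nd percentile, just inside the limit, and stood apart with a pseudocount of 5, with 10 bins and with the length and GC trend removed. The reference genes had a median of -0.10, and it was -0.00057 with total count CPM.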

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

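The comparison of transcript models within a locus was chosen only after the deposited files had been seen, and it was not corrected for the number of loci compared. In the counts per model, which were summed for all comparisons between the libraries, the share of the first model was set side by side for the 344 loci with 2 listed models and at least 100 reads in each library. The 95% exact intervals of the 2 libraries lay apart at 4 of them. For CAT2, a peroxisomal catalase, the first model took 97.0% of reads in Col-0 and 99.1% in FMO5-OE. For ARF2, an auxin response factor, it took 2.88% and 12.5%, on 4 and 20 reads. For AGP9, an arabinogalactan protein, the shares were 67.6% and 84.1%. For AT3G15450, an aluminum-induced protein, they were 57.7% and 75.4%. With reads shared between models left out, these shares describe only the reads that tell the models apart.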

How the results depend on the processing

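Single-model loci, the model with most reads and the length and GC trend were chosen only after the data had been seen. No paired analysis was possible because there was 1 library per genotype, and the groups share a single replicate number given in accession order. FMO GS-OX5 kept its direction in every alternative that could be run, and single-model loci gave no value for it. With a pseudocount of 5 its log2 ratio was 3.93. No list that stood apart changed sign. Of 570 list medians under alternatives, 551 stayed within their interval, and of 1769 values of named genes 1703 did, with 0 changes of sign among genes at least 2-fold apart.

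The number of loci higher and lower ran up to 140 and 57 with a pseudocount of 0.1 and was 131 and 59 at a minimum of 1 CPM or none. It moved to 42 and 17 with a pseudocount of 5, to 56 and 21 at a minimum of 20 CPM and to 16 and 3 with the 3-fold rule, as larger limits count fewer loci. The interquartile range was 0.35 with a pseudocount of 0.1, 0.28 with 5, 0.31 at a minimum of 20 CPM and 0.31 with the trend removed. The median of all loci was -0.00501 with DESeq2 size factors, 0.075 with equal nuclear totals, 0.0805 with total count CPM and -0.025 at 20 CPM. The number of lists lower fell from 10 to 6 with the trend removed.

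Among list medians, a pseudocount of 5 gave 0.10 for ABA and drought, -0.38 for iron deficiency and 0.20 for disease resistance. Equal nuclear totals gave 0.17 for the evening clock, -0.14 for photosynthesis, 0.25 for WRKY factors, 0.13 for cytochrome P450 enzymes and 0.064 for the defensin pattern. Total count CPM gave 0.18, -0.13, 0.26, 0.14 and 0.068 for these, -0.00057 for reference genes and 0.030 for expansins. A minimum of 5 CPM gave -0.40 for flavonoid synthesis. Leaving out loci with a neighbour of the same product gave -0.12 for lipid transfer proteins. Removing the trend gave -0.10 for photosynthesis and 0.22 for disease resistance. Apart from scalings, which shift all genes alike, the cause was not tested. Depth limited low genes: 5 CPM stood for 55.9 reads in Col-0.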

Other observations

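The tests on root tissue, on time of day, on read number and on reads shared with other loci, the minimum of 100 reads per model, and the removal of the length and GC trend, were chosen only after the result was seen. Several gene families were higher in FMO5-OE. Disease resistance proteins with nucleotide-binding domains had a median log2 ratio of 0.30 (0.24 to 0.39), with 100 of 121 above 0, and AT1G66090 was 2.93-fold higher. In this list 46 loci have a neighbour of the same product. Cysteine-rich receptor-like kinases had a median of 0.23, with CRK4 4.37-fold and CRK10 2.07-fold higher, WRKY factors 0.18, with WRKY70 2.37-fold higher, and NAC factors 0.19, with ORE1, a regulator of leaf senescence, 1.87-fold higher. With a pseudocount of 5 these medians were 0.20, 0.15, 0.12 and 0.10. Cytochrome P450 enzymes had a median of 0.05 (-0.004 to 0.11), with an interval that spans 0, or 0.14 with total count CPM. Their call ended in 5 of 13 alternatives.

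Lipid transfer proteins had a median of -0.28 with 52 of 67 below 0. The call ended, at -0.12, without loci that have a neighbour of the same product. Ethylene response factors had a median of -0.12 (-0.23 to 0.08), although AT5G51190 and ERF6 were 3.34-fold and 2.79-fold higher. HSP20-like proteins had a median of -0.19 (-0.23 to 0.03). The intervals of both medians span 0. Both calls ended at a minimum of 5 CPM and with the length and GC trend removed, where the medians were -0.051 and -0.053, and equal nuclear totals gave -0.027 and -0.10. The call of ethylene response factors also ended without a minimum on members, at -0.038. Chloroplast-encoded loci at 5 CPM or more had a median of -0.28, with 48 of 66 below 0, and mitochondrion-encoded ones 0.02. The remaining lists did not stand apart: medians were -0.02 for salicylic acid defence, in which WRKY70 was higher and ALD1 2.42-fold lower, -0.06 for jasmonate and ethylene defence, 0.05 for mitochondrial stress, -0.11 for glutathione transferases, -0.10 for flavonoid synthesis, 0.18 and 0.11 for the morning and evening clock, -0.03 for root markers, -0.07 for peroxidases, -0.07 for late embryogenesis abundant proteins, -0.01 for the defensin pattern, -0.13 for xyloglucan transglucosylases, -0.07 for expansins and 0.14 for the FMO family. Of these, the morning clock stood apart with a pseudocount of 5 and at a minimum of 5 CPM, flavonoid synthesis at 5 CPM, late embryogenesis abundant proteins with a pseudocount of 5, and peroxidases and xyloglucan transglucosylases without a minimum. Only 1 seed storage gene was measured.

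The sugar starvation, sulfur, phosphate and rapid stress lists were higher and the iron list lower. After removal of the length and GC trend the list that lost most kept 0.941 of its median. That trend thus does not account for the pattern. Without loci of several models or with a neighbour of the same product, 5 of 5 lists stayed outside the random range. The iron median was then -0.54. Where such loci were removed, they do not account for the pattern. The phosphate list held 0 such loci, so nothing was removed from it, and only the iron list had members with marked neighbours. The mark does not see overlaps on opposite strands, so reads shared in that way were not tested. A smaller share of root tissue would lower root markers with the iron list, but the interval of their median began at -0.57, above the iron median of -0.69, and the difference of the medians was 0.66 (bootstrap interval 0.22 to 1.16). The morning and evening clock medians differed by 0.071 (bootstrap interval -0.14 to 0.44), so the medians lay less than 0.5 apart. The bootstrap treats the 7 measured genes of each list as independent. The intervals of the 2 medians reached down to -0.79 for the morning and -1.08 for the evening list. A median can hide members that moved, so this comparison does not decide on the time of day at harvest. A difference in nutrient or sugar state, from the genotype or from the plates, may underlie the sugar, sulfur, phosphate and iron lists. This was not tested, and it is not offered for the rapid stress list. With 1 library each, genotype and plates cannot be separated.

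FMO GS-OX5 had many reads on a small part of its model. Too few reads is not the reason, since 1610 single-model loci with a like read count had a median coverage of 96.7%. Across 19 models of 2-model loci with 100 or more reads, which are not independent replicates, the covered share followed the share of sequence absent from the other model with a Spearman correlation of 0.909, and it was 0.842 over 123 models at a minimum of 20 reads. Reads shared with model 2 may therefore have been left out, yet the 8.15% covered is at most 24.2% of the sequence absent from model 2. This is below the lowest of the 19 models, 46.4%. The lowest was 25.2% over 45 models at a minimum of 50 reads. At a minimum of 20 reads it was 6.76% over 123 models, of which 2 lay below FMO GS-OX5. AT1G12150 overlaps the gene on the other strand, and of the sequence absent from all other listed models at most 63.1% was covered. This is within the range of the 19 models but below the lowest of 8 models with 200 or more reads, 74.6%. The listed length of AT1G12150 differs from the annotated one by 3 bases. It is thus a partner of another length, a class in which 25 of 218 loci were covered over 5 points beyond their own share. Leaving out reads shared with either may account for much of the small coverage, but other reasons were not tested. The level rests on few bases in both libraries.

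The pseudogene AT5G35935 (chromosome 5, 14083388 to 14089891, TAIR10.1), named after its value was seen, had 9 reads in Col-0 and 324 in FMO5-OE, 31.9-fold more (16.6 to 70.4). Annotated pseudogenes at 1 CPM or more as a class had a median of 0.089 (0.03 to 0.13), so a general difference in such loci does not account for it. No other explanation was tested, and a difference of this locus between seed stocks or an effect of the transgene may each apply.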
